A study of Homo sapiens with 2 samples.

How the data were processed

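Total RNA from exosomes of K562 cells was measured on 2 arrays, 1 per isolation method. Per the labels' protocols, cells were moved from serum-containing medium to serum-free AIM V medium, and the medium was collected after 24 h. For the Exoquick sample the filtered medium was kept cold with the reagent for 12 h and spun at 1500 × g for 30 min. For the other sample the medium was cleared by slower spins and ultracentrifuged at 110000 × g for 70 min. Per the labels, 100 ng of total RNA was labelled at its 3' end with Cy3-pCp, so equal RNA mass rather than equal medium was compared. Groups were taken from the sample titles. Both arrays lay on the same slide, so the array position and the group cannot be told apart.

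Per the file headers, the authors' scans were read with Agilent Feature Extraction 10.7.3.1 under its microRNA protocol miRNA_107_Sep09, on array design 021827, with hg19 in the genome build field. The deposited intensity values are 1-colour spot intensities on a linear scale, background-subtracted and spatially detrended within each array and not normalized between arrays. Flags with values of 0 or 1, as deposited per the file headers, mark spots that are well above background, saturated or outliers. The deposited series value table holds intensity as well. Of its 961 names, 941 were scanner names with values equal to the software's total gene signal on both arrays, 12 matched after a version suffix was removed, and 8 matched by neither. It is therefore linear and uncentred, and each column had a median of 0.1, the value the software writes for microRNAs below detection. All columns of this table were mapped to a sample by name. Later steps by the authors are not given in the sources used here.

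From the processed intensity, control spots were left out, as were spots with an outlier flag (7.56% of the spots with Exoquick and 6.75% with ultracentrifugation). Spots of a probe were averaged. A probe counted as detected when more than a share of 0.5 of its spots were well above background, and a microRNA when any of its probes was. Of 2689 probes, 458 were detected with Exoquick, 198 with ultracentrifugation and 178 on both. Each array was divided by the 75th percentile over those 178 probes. The probe means of a microRNA were then summed and put on the log2 scale. Differences were taken for microRNAs detected on both arrays, and for the others the brightest probe was set against the higher of the dimmest detected probe and the probe's own signal on the other array, which is a lower bound where the ratio is above 1. SEs come from the spread of the spots of each probe. A microRNA was called higher or lower when its log2 difference was at least 1 and above 2 SE. This is a rule of size, not a test. Names are those of the array design, with version suffixes dropped.

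The percentile of a list's median was found among 10000 random lists of the same size, matched on mean signal in 5 bins and drawn from the entries detected on both arrays, and describes these arrays only. To judge shifts under the alternatives, 95% intervals of the correlations, SD and median over all shared microRNAs were found by resampling microRNAs 1000 times, and those of list medians from the ordered values of the members (their full range in the smallest lists). These intervals cover no difference between preparations. The groups, the main setting, 14 lists, the rule for named microRNAs and the alternatives were chosen before the data were examined, except where stated. The lists cover the miR-17/miR-92a family clusters, let-7, erythroid and haematopoietic microRNAs, plasma Argonaute2 carriers, miR-320 and vesicle-associated microRNAs, fragments of other RNAs, G- and C-rich entries, markers of muscle and liver, epithelium, mesenchyme and endothelium, neural tissue and pluripotency, viral entries and star strands. They overlap. For example, miR-630 and miR-638 are in the vesicle-associated and the G- and C-rich list, miR-1246 is in the vesicle-associated and the fragment list, miR-122 is in the Argonaute2 and the muscle and liver list, and miR-16 and miR-92a are in more than 1 list. Star strands of other lists, such as miR-149* and miR-150* of the G- and C-rich list and miR-17* of the miR-17/miR-92a list, are also among the star strands. Named microRNAs are miR-92a, the 10 with the largest difference in each direction, the 5 with the largest bound in each direction, the highest and lowest member of each list, and further members of the miR-17/miR-92a, let-7 and haematopoietic lists. Others, such as those whose probes went in opposite directions, were named after their values were seen.

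Alternatives were the percentile over all probes, no scaling, the median difference (over human and viral entries) set to 0, quantile normalization, scaling on the 4 dmr control probes with signal, the software's total gene signal, the series value table, other ways to combine probes and spots, other detection rules and other size limits. Normexp background correction on the median signal with an offset of 50 was added after the files were seen. The dmr control probes were brighter by 0.32 (log2) with Exoquick. Whether they measure RNA added in equal amounts is not given in the sources used here. The floor for microRNAs below detection was first set per array, which called many undetected microRNAs lower, and was then made 1 common floor. Bounds without scaling and with the dmr control probes, and list counts with normexp, were also added after the data were seen. Membership of the G- and C-rich list was set by name and not checked against sequences. List medians were limited, also after the data were seen, to lists with 2 or more shared members.

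The calculation was tested on 2 simulated arrays, both built from the signals of 939 entries on the Exoquick array, 1 of them dimmed. Only entries bright enough to stay detected were changed, as many up as down, and only spot noise was added. The simulation therefore checks the calculation, not the choice of scaling or differences between preparations. All 24 entries changed 4-fold were called in the right direction, 0 unchanged entries were called, and the unchanged entries had a median difference of -0.06. The signal limit for simulated changes was loosened once so that more entries could be changed. Gene order around MEG3 was read from a RefSeq table of assembly GRCh38.p14, used only for names and neighbours, so positions are not given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.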

Results

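The RNA carried by exosomes of K562 cells, a human line derived from chronic myelogenous leukaemia, was profiled on 2 one-colour microRNA arrays. Exosomes are small vesicles that cells release into their medium. In one sample they were recovered from conditioned medium with Exoquick, a polymer reagent that precipitates vesicles, and in the other they were pelleted by ultracentrifugation. Each group held 1 array, so the comparison asks how the microRNA profile of these 2 preparations differed, and no p-value or replicate check was possible. The number of arrays limits the precision. Each error below is a standard error (SE) from the spread of the spots of a probe, which covers noise between spots of the same array and nothing between preparations. All differences are Exoquick minus ultracentrifugation on the log2 scale, after each array was divided by the 75th percentile of the probes detected on both.

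Each array carried 15739 spots, 15024 of them for 851 human microRNAs and 88 viral microRNAs. Spots well above background made up 20.4% of these on the Exoquick array and 9.33% on the ultracentrifugation array, and no spot was saturated. The 75th percentile used for scaling was 864 intensity units with Exoquick and 258 with ultracentrifugation, a ratio of 3.35. The negative control spots had a mean of 5.93 units with Exoquick and 5.96 with ultracentrifugation.

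More microRNAs were detected in the Exoquick preparation. It gave 230 human microRNAs (27.0% of those on the array), against 107 (12.6%) after ultracentrifugation. Both arrays detected 101 of them, 129 were detected with Exoquick only, 6 with ultracentrifugation only, and 615 on neither array. The let-7 family, which acts in differentiation and restrains growth, had 9 entries on the array, and all 5 detected were among those found with Exoquick only, namely let-7a, let-7b, let-7e, let-7f and let-7i. After scaling, let-7b was at least 2.23-fold higher, let-7a at least 1.27-fold and let-7f at least 1.09-fold, and let-7e and let-7i had no bound.

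The microRNAs shared by both preparations differed in both directions. Of the 101 detected on both arrays, 38 were at least 2-fold higher with Exoquick by more than 2 SE, 32 were at least 2-fold lower, and 31 met neither criterion. The highest relative to ultracentrifugation were miR-1826, an entry whose sequence lies in ribosomal RNA, with a difference of 2.78 ± 0.10 (6.88-fold), miR-22 with 2.77 ± 0.08 (6.80-fold), miR-574-5p with 2.67 ± 0.05 and miR-130b with 2.63 ± 0.06. The ultracentrifugation level of miR-1826, 0.068, lay under the dimmest detected probe there (0.073). From the brightest probe alone miR-1826 stood at 2.48, below miR-1182 (3.03), miR-22 (2.76), miR-21 (2.65), miR-130b (2.62), miR-574-5p (2.60) and miR-223 (2.55). With the total gene signal it stood at 2.25, below miR-22 (2.76), miR-1182 (2.65), miR-224 (2.64), miR-574-5p (2.44), miR-130b (2.40), miR-21 (2.37) and miR-223 (2.33). The growth-promoting miR-21 followed with 2.60 ± 0.03 (6.08-fold), then miR-223, a myeloid microRNA, with 2.56 ± 0.02. The rest of the 10 highest were miR-16 with 2.35, miR-224 with 2.30, miR-1182 with 2.25 and miR-107 with 2.21. The value of miR-1182 depended on how probes were combined, with 1.56 from the mean of the log2 probe values.

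The lowest with Exoquick in the main setting was miR-630, with a difference of -4.18 ± 0.02, or 18.2-fold lower. After miR-630 came miR-583 with -4.08 ± 0.10 (17.0-fold lower), miR-422a with -3.78 ± 0.08 (13.7-fold lower) and miR-720, a fragment of a transfer RNA, with -3.72 ± 0.03 (13.2-fold lower). The minor strand miR-30c-2* stood at -3.42 ± 0.06, miR-765 at -3.07, miR-654-5p at -3.04, miR-1260 at -2.89, miR-760 at -2.77 ± 0.17 and miR-1274a at -2.75. The 4 probes for miR-760 lay 1.29 apart, from -3.23 to -1.94. The order of these entries depended on the processing. With quantile normalization miR-630 stood at -2.80, behind miR-583 (-4.19), miR-422a (-3.86) and others. With the total gene signal miR-583 (-4.54) lay below miR-630 (-4.41). For miR-422a the difference was -3.24 from the brightest probe alone and also from the mean of the log2 probe values.

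The scaling decided how many microRNAs counted as higher or lower. The split was 38 higher to 32 lower (54.3% higher) as given above, 42 to 23 (64.6%) with the percentile taken over all probes, 59 to 12 (83.1%) with the arrays set equal on the dmr control probes, and 65 to 10 (86.7%) without scaling. Normexp background correction, tried after the data were seen, gave 17 to 37 (31.5%), with 6 of the 10 highest still called. The difference fell to 0.35 for miR-1826, 0.60 for miR-224, 0.48 for miR-1182 and 0.13 for miR-107. The median difference, 0.087 as given above, shifted by 0.47 with all probes, by 1.42 with the dmr control probes, by 1.75 without scaling, by 0.11 with the median of all differences set to 0 and by -0.22 with quantile normalization. Under all 6 scalings, 35 microRNAs were higher and 10 lower by the same criterion, and those 10 were the same 10 lowest named above. Of the 32 called lower, 12 changed sign without scaling and 7 with the dmr control probes. Apart from quantile normalization, these scalings add a positive constant to every difference, so they could not turn a higher call. With normexp, 16 of the 38 called higher were still called higher. Of these 38, 3 fell below 0 (miR-299-3p, miR-425 and miR-654-3p, named after their values were seen). All 32 called lower were still called lower. The normexp offset was added to every spot, and the brighter Exoquick array was divided by more, which draws dim entries towards a negative difference. Keeping the lower calls and losing higher ones therefore does not show that the lower calls are the more stable.

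**Figure D1:**
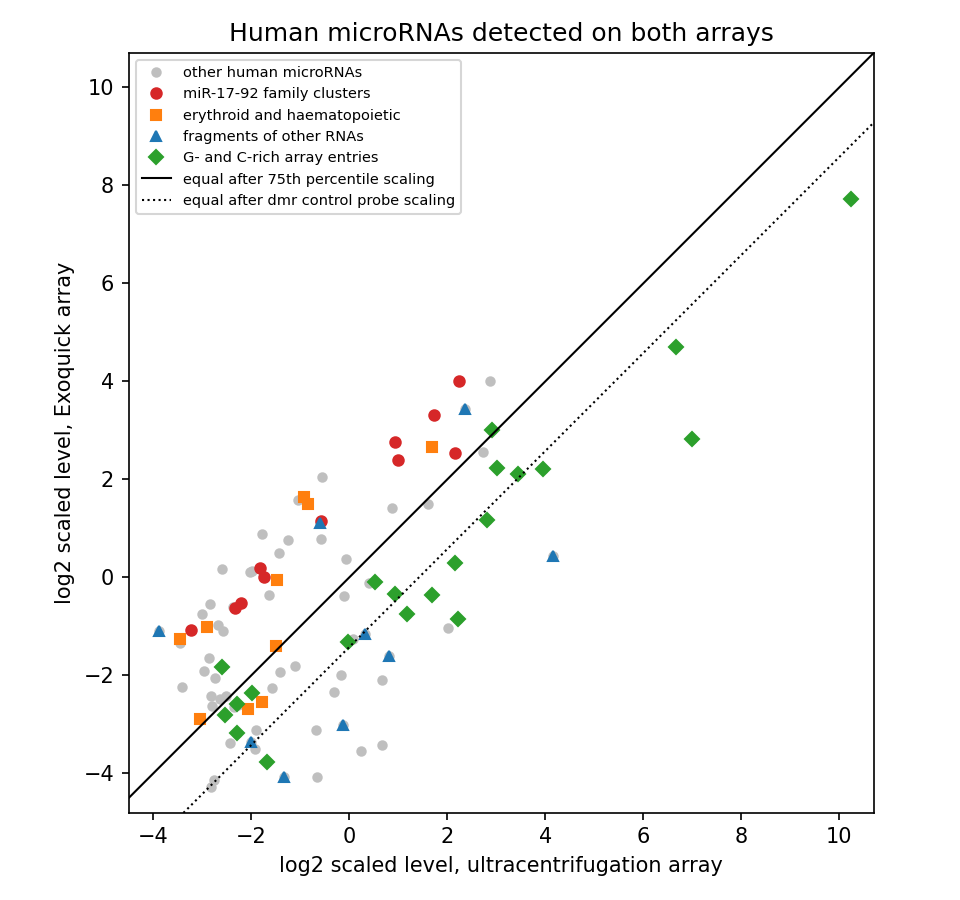
Log2 scaled level of each of the 101 human microRNAs detected on both arrays, with the ultracentrifugation array on the x axis and the Exoquick array on the y axis, 1 point per microRNA and 1 array per axis. Members of the miR-17/miR-92a family clusters lie above the solid line of equality, and most G- and C-rich entries lie below it, although their median turns positive after scaling on the dmr control probes, for which the dotted line marks equality.

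Across these 101 microRNAs the levels on the arrays had a Pearson r of 0.71 and a Spearman rho of 0.59 on the log2 scale. These are correlations across microRNAs, which are not independent replicates. The differences had a standard deviation of 1.84 and ran from -4.18 to 2.78, against a median SE of 0.045 and a largest SE of 0.17. Of 61 entries, human and viral, with 2 or more probes detected on both arrays, 4 had probes more than 1 apart. The probes went in opposite directions for 2 entries, miR-423-5p (from -1.83 to 0.47) and miR-1207-5p (from -0.29 to 0.37).

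For microRNAs detected on only 1 array, the brightest probe was set against the higher of its own signal and the dimmest probe well above background on the other array. This gave a lower bound for 52 of the 129 found with Exoquick only and for all 6 found with ultracentrifugation only, and none for the other 77 after percentile scaling. Bounds of 2-fold or more were reached by 18 and 6 of them. Without scaling these counts were 92 and 1, and with the dmr control probes 76 and 1, the 1 being miR-516b in both cases. With Exoquick the largest bounds were for miR-595 (at least 4.65-fold higher), miR-146b-5p (at least 4.18-fold), miR-29a (at least 3.88-fold), miR-495 (at least 3.79-fold) and miR-27a (at least 3.77-fold). With ultracentrifugation they were for miR-516b (at least 13.3-fold higher), miR-125b-2* (at least 5.34-fold), miR-632 (at least 5.17-fold), miR-658 (at least 4.75-fold) and miR-202 (at least 4.35-fold). Without scaling the bound was 3.97-fold for miR-516b and 1.59-fold for miR-125b-2*, and the largest Exoquick bound, for miR-595, was 15.6-fold.

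The miR-17/miR-92a cluster and its paralogous clusters, which drive proliferation in blood cancers, were higher with Exoquick after percentile scaling, in part below 2-fold with normexp. Of 19 entries on the array, 11 were detected on both arrays, 4 with Exoquick only and 4 on neither. By the criterion of size and SE, 10 of the 11 were higher and 0 lower, with miR-93 at 2.17 ± 0.05, miR-17 at 1.83 ± 0.06, miR-20b at 1.76 ± 0.04 and miR-19a at 1.40 ± 0.03. The median was 1.74, at the 98.6th percentile of random lists of like signal. Members of a cluster and its paralogues are not independent of each other, which the random lists do not take into account. With normexp 5 of the 11 were higher, miR-93 stood at 0.28 and miR-18b, the lowest, at 0.15, and the list median was 0.96, at percentile 99.2. The median was 3.16 with the dmr control probes and 3.48 without scaling.

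The lowest member of this group was miR-92a, the microRNA named in the series' design text. Its difference was 0.38 ± 0.03, or 1.30-fold, under the 2-fold limit. It was 1.80 with the dmr control probes and 2.12 without scaling. With normexp it was 0.48, above miR-18b, miR-93 and miR-106b (0.39), and so no longer the lowest. Those were the dimmest shared members with ultracentrifugation (scaled levels of 0.22, 0.11 and 0.20, against 4.45 for miR-92a), where the normexp offset weighs most. The other shared members stayed above miR-92a, from 0.76 to 1.84. In its account of the ultracentrifugation preparation, the design text names cells given a Cy3-labelled miR-92a precursor beside plain K562 cells, while both sample labels name K562 alone. Which cells supplied that array therefore rests on the labels.

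MicroRNAs of erythroid and other blood lineages were in part higher with Exoquick. Of 21 on the array, 10 were detected on both arrays and 2 with Exoquick only. The array's miR-103a, also found with Exoquick only, did not match the listed miR-103 by name and was not counted. Of those 10, 5 were higher and 0 lower, among them miR-223 (2.56), miR-16 (2.35), miR-15a (1.89 ± 0.05) and miR-15b (1.43 ± 0.02). The erythroid miR-451 had a difference of 0.98 ± 0.02 and miR-486-5p 0.10 ± 0.04, while miR-210 had -0.62 ± 0.05 and miR-486-3p, the lowest, -0.77 ± 0.08. These last 2 turned positive with the dmr control probes (0.80 and 0.65) and without scaling (1.12 and 0.98). With normexp 3 were higher and 2 lower, miR-15a stood at 0.22 and miR-15b at 0.59. The median of 1.21 lay at the 80.7th percentile of random lists, and it was 0.18 with normexp, 2.63 with the dmr control probes and 2.95 without scaling.

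Of 3 microRNAs that travel in plasma mainly with Argonaute2 protein outside vesicles, miR-16 was 5.09-fold higher with Exoquick, miR-92a was 1.30-fold higher, under the limit, and miR-122 was detected with Exoquick only. The median of the first 2 was 1.36, and it was 2.78 with the dmr control probes and 3.11 without scaling. All 9 microRNAs on the array from the list often reported in vesicles of cell lines were detected on both arrays, 4 of them higher and 3 lower. Of the higher ones, miR-320d had 1.36 ± 0.03, though 0.87 with normexp, and miR-630 was the lowest of the list. The median of this list was 0.69, at the 71.9th percentile of random lists, but its mean was -0.16. The median was 2.11 with the dmr control probes and 2.44 without scaling. It turned to -0.040 with normexp and to -0.71 over microRNAs with every probe detected on both arrays.

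Entries that derive from other RNAs went both ways. Of 10 on the array, 9 were detected on both, with 3 higher and 6 lower. Of the lower entries, miR-720, miR-1260 and miR-1274a were among the 10 lowest human microRNAs and lower under every scaling. Of the other lower entries, miR-1274b stood at -2.41, miR-886-3p at -1.47 and miR-1280 at -1.36, but without scaling at -0.67, 0.28 and 0.38. The entries miR-1308 (1.69) and miR-1246 (1.06) were higher under every scaling. The remaining higher entry, miR-1826, was the highest human microRNA in the main setting. It stood at 0.35 with normexp and behind miR-22 and several others with the total gene signal. The median was -1.47, at the 3.80th percentile of random lists, but it was -0.049 with the dmr control probes and turned to 0.28 without scaling, both with 3 higher and 3 lower. Over microRNAs with every probe detected on both arrays it was -3.07.

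A list of entries commonly bright on this type of array, named for the many among them that are rich in G and C, was lower with Exoquick after percentile scaling, with a median of -1.32, but its direction turned to 0.10 with the dmr control probes and to 0.43 without scaling. Of 27 on the array, 21 were detected on both arrays and 4 with Exoquick only. Of those 21, 0 were higher and 13 lower, from miR-630 at -4.18 to miR-134 at 0.77 ± 0.08. With the dmr control probes 5 were higher and 3 lower, and without scaling 6 were higher and 2 lower. The median lay at the 3.36th percentile of random lists.

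Markers of other tissues were mostly below detection. Of 8 muscle and liver microRNAs, miR-122 of liver and miR-206 of muscle were detected, with Exoquick only. None (0) of 7 epithelial microRNAs was detected on either array. Of 8 mesenchymal and endothelial microRNAs only miR-126 was, on both arrays, with a difference of 0.44 ± 0.04. Of 8 neural microRNAs miR-128 and miR-129-5p were found with Exoquick only, as was miR-371-5p alone of 9 microRNAs of the pluripotency clusters.

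Minor strands, marked with a star, were rarely shared. Of 171 on the array, 6 were detected on both, 22 with Exoquick only and 1 with ultracentrifugation only. Of the 6 shared, miR-32* was higher (2.11 ± 0.09, but 0.35 with normexp) and 5 were lower. Their median was -1.86, at the 1.495th percentile of random lists, and it was -0.44 with the dmr control probes and -0.12 without scaling. Of the 88 viral entries, 4 were detected on both arrays, 10 with Exoquick only and 2 with ultracentrifugation only. An Epstein-Barr virus entry, ebv-miR-BART12, was higher with Exoquick (2.77 ± 0.20, but 0.76 with normexp), and 3 viral entries were lower, down to hsv1-miR-H1 at -2.51 ± 0.03. The viral median was -1.78, at the 9.64th percentile of random lists, against -0.36 with the dmr control probes and -0.032 without scaling.

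**Figure D2:**
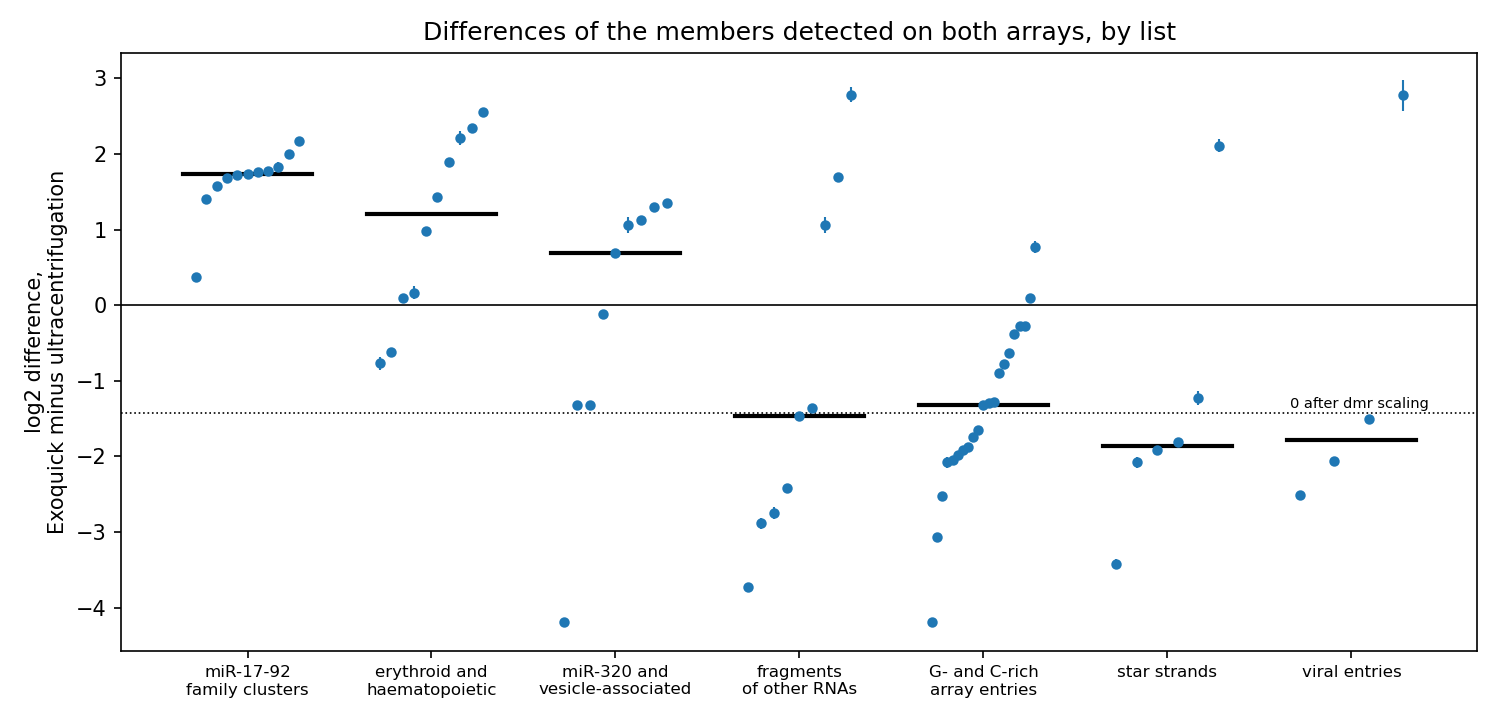
Log2 difference, Exoquick minus ultracentrifugation, of each list member detected on both arrays, with bars for the SE over spots, thick lines for list medians and a dotted line where 0 would lie after scaling on the dmr control probes. The miR-17/miR-92a members lie between 0.38 and 2.17 and stay positive under every scaling, most of which raise all differences, whereas the G- and C-rich median of -1.32 lies just above the dotted line and so turns positive with that scaling.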

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

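The tests of a single factor, of spot noise and of binding independent of the sample were chosen after their results were seen, and the test of a signal-dependent response was set before its result was seen.

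Of the control probes outside the comparison named hur and mr in the array design, hur_1, hur_2, hur_4, hur_6 and mr_1 gave signal above that of the negative control spots on both arrays. The mean plus 3 SD of those spots was 19.8 units with Exoquick and 19.0 with ultracentrifugation. Before scaling, hur_1 read 14040 with Exoquick and 4236 with ultracentrifugation, hur_2 read 23901 and 5750, and hur_4 read 5655 and 1031. By contrast hur_6 read 761 and 745, and mr_1 read 2467 and 2807. The remaining probe, hur_5, read 9.53 and 2.30, below those limits. The ratios of Exoquick to ultracentrifugation were therefore 3.31, 4.16 and 5.49 for the first 3, and 1.02 and 0.879 for the last 2. What these probes target is not given in the sources used here.

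Part of the microRNAs were higher and part lower with Exoquick, relative to each other. One factor for the whole array would put the unscaled differences on one side, but 9.90% of the shared human microRNAs (10 of 101) were at least 2-fold brighter with ultracentrifugation before scaling, while 65 were brighter with Exoquick. A response that depends on signal alone keeps the order of microRNAs, and the Spearman rho of 0.59 (95% interval over resampled microRNAs 0.445 to 0.701) lay under the 0.8 set as its limit. Spot noise was too small, with a median SE of 0.0243 times the SD of the differences. The isolation method may account for the pattern, but with 1 array per method it cannot be told apart from differences between cultures, RNA extractions, labelling reactions or array positions, none of which was tested.

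G- and C-rich entries, and most of the few shared viral entries, were lower with Exoquick after percentile scaling, while the G- and C-rich median turned positive with the dmr control probes and without scaling. Binding that does not depend on the sample RNA could leave such probes equally bright on both arrays, so that scaling a brighter array down would make them look lower. The unscaled medians were near 0, with 0.43 for the G- and C-rich entries and -0.032 for the viral entries, but they decide little. Of the 21 G- and C-rich entries, 8 (38.1%) were at least 2-fold apart before scaling, 6 brighter with Exoquick and 2 with ultracentrifugation. Only 4 viral entries were shared. Of those 4, 1 was at least 2-fold brighter with Exoquick before scaling (ebv-miR-BART12, with a log2 difference of 4.52) and 0 with ultracentrifugation. A true difference in RNA content between the preparations stays open and was not tested.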

How the results depend on the processing

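Normexp and the bounds under other scalings were chosen as alternatives after the data were seen, as were the common floor and the limit on list sizes, and the other alternatives were set beforehand. Normexp on the mean signal was not run, because the scanner files read here have no column for it, and the median signal was used instead. No paired analysis was possible because each group held 1 array. Among counts, correlations and medians under the alternatives, 171 stayed within 1.5 times (counts) or a 95% interval over microRNAs, 26 moved and 2 reversed beyond it. Medians changed sign in 8 cases, those 2 included, such as the fragment median without scaling (0.28), the vesicle-associated median with normexp (-0.040) and the median of all differences with quantile normalization (-0.13). Part of the 171 was fixed in advance, since correlations and the SD do not change when a constant is added. The intervals of the smallest lists span their full range and are hard to leave. Of single differences 144 stayed within their spot error and 404 moved, and with normexp 3 of the 38 called higher fell below 0. Without scaling 65 were higher and 10 lower, with a median of 1.83 and list medians of 3.48 (miR-17/miR-92a), 2.95 (haematopoietic), 3.11 (Argonaute2) and 2.44 (vesicle-associated), and the G- and C-rich median reversed to 0.43. With the dmr control probes 59 were higher and 12 lower, with a median of 1.51 and list medians of 3.16, 2.63, 2.78 and 2.11 in the same order, and the G- and C-rich median reversed to 0.10. Both settings add a constant to every difference, which is the cause. The percentile over all probes, also a constant, gave a median of 0.56 and 2.21 for miR-17/miR-92a. Normexp gave 17 higher, an SD of 1.28, a median of -0.62 and 0.96 for miR-17/miR-92a. It added 50 units to every spot before scaling, and the brighter Exoquick array was divided by more. This pulls dim entries towards lower with Exoquick, but its share of these changes was not tested. With every probe detected on both arrays, 50 microRNAs remained. Of these, 13 were higher and 18 lower (41.9% higher, against 54.3% in the main setting). The median difference was -0.45 and the fragment median -3.07. With 851 microRNAs at a floor 70 were higher, Pearson r was 0.84 and the SD 0.76, as most lay at the floor on both arrays. The counts of detected microRNAs stayed within 1.5 times under 3 other detection rules. The dimmer ultracentrifugation array, with 9.33% of spots well above background, limits what can be compared. Of 129 microRNAs found with Exoquick only, 52 had a bound after percentile scaling, and 18 one of 2-fold or more, against 76 with the dmr control probes and 92 without scaling.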

Other observations

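The cluster was chosen as a group after values of its members were seen, while its tests of a chance draw and of serum RNA were set before their results were seen; the hairpins and miR-92a's place in its family were also picked after their values were seen.

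The imprinted cluster beside MEG3, a large group of microRNAs expressed from the maternal chromosome, was well represented with Exoquick. Of 64 entries from the 52 microRNA genes between MEG3 and DIO3, 37 (57.8%) were detected with Exoquick and 13 (20.3%) with ultracentrifugation, against 24.5% and 11.9% of the other human entries. Entries were matched to genes by name. Detected with Exoquick only, miR-323-3p was not matched and was counted among the other human entries. All 13 were shared, and 7 of them were higher and 2 lower, with 11 higher and 1 lower without scaling and 2 higher and 2 lower with normexp. The highest was miR-377 with 2.13, followed by miR-376c with 2.02, miR-376a with 1.93, miR-381 with 1.75 and miR-127-3p with 1.47. The lower ones were miR-654-5p with -3.04 and miR-370 with -1.57.

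Of 3 hairpins with both arms shared between the arrays, miR-654 had arms in opposite directions, with 1.23 ± 0.05 for miR-654-3p and -3.04 ± 0.02 for miR-654-5p, and this held with the dmr control probes (2.65 and -1.62) and without scaling (2.98 and -1.29), but with normexp both were negative (-0.23 and -2.48). The arms of miR-299 read 1.06 and -0.28, and those of miR-486 read 0.10 for the 5p arm and -0.77 for the 3p arm, but without scaling all 4 were positive.

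Within the miR-17/miR-92a clusters, miR-92a at 0.38 lay below the other 10 shared members, which ran from 1.40 to 2.17, but with normexp it was 0.48 and lay inside their range of 0.15 to 1.84. The members below it with normexp were the dimmest with ultracentrifugation, where the offset weighs most. RNA of the cells with the Cy3-labelled precursor, had it been on the ultracentrifugation array, could raise the miR-92a signal and the Cy3 signal there. The labels name K562 alone, and this was not tested.

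The shared members of the cluster beside MEG3 had a median difference of 1.06 in favour of Exoquick, which turned to -0.23 with normexp. A chance draw of microRNAs of like signal could give this, since the median lay at the 90.1th percentile of random lists, inside the range of 95% of them. RNA from the serum of the earlier culture is another candidate source, and of 8 muscle and liver markers 2 were detected with Exoquick, too few to tell, since such markers could lie under the detection limit. The pattern was narrowed to members higher with Exoquick after the detection counts were seen. The random lists held only entries detected on both arrays, so the larger share of the cluster detected with Exoquick was not tested against chance. Release of these microRNAs in particles that only Exoquick recovers was not tested, since the isolation method and the array cannot be told apart.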
